A study of Apis mellifera with 177 samples.

How the data were processed

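RNA was measured in whole brains of 177 worker honey bees (Apis mellifera), each brain a separate library. The bees came from 9 colonies named after the places in Puerto Rico where the colonies originated. All had been moved to a common field station before sampling. The labels gave each bee's colony, its behaviour (soldier or forager), a replicate number, the strand to which read 1 aligned, and 2 scores of its colony, called here the aggression score and the consistency score. Samples were grouped by colony and behaviour, which gave 18 groups of 9 or 10 bees.

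The deposited files hold read counts per gene, raw and not normalized, in 1 file per bee. Per the submitters' processing notes, STAR 2.7.3a, featureCounts and Subread 2.0.0 were used, and Salmon was also named; their settings, the annotation release and the genome build are not given in the sources used here. Per the file headers' columns, each count covers the whole span of a gene, so that reads from introns and from genes nested in or overlapping a gene cannot be separated from its exons. How reads that align to several places were counted is not given in the sources used here, so that counts of near-identical copies are uncertain. Whether the authors counted by strand is not given in the sources used here, so neighbouring genes on opposite strands may share reads. Each file had 12337 features, of which 5 were viruses. Of the 12332 bee features, 12326 were paired with a symbol by comparing the start and end of the feature with the reference table of the Amel_HAv3.1 assembly, and 6 were left without a name. Most symbols were LOC numbers, and 831 features had another symbol. The table gives no product names for LOC genes, so their function is not described. Coordinates are those of the deposited files, which matched that assembly.

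The total count per library over bee genes ran from 6166138 to 19537168 with a median of 14969046 in 176 libraries. The remaining library, Patillas2 soldier 9, held 24647 counts. It stayed in the main tests, as fixed before the data were examined, and was left out in an alternative. Read 1 aligned to the antisense strand in 95 libraries and to the sense strand in 82. This split was treated as a library batch, and each of the 18 groups held both batches. Virus features were kept out of library sizes and gene tests.

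Gene tests were made in R 4.3.3 with edgeR 4.0.16. Low counts were removed with filterByExpr for the design of each fit, libraries were scaled by TMM, and glmQLFit and glmQLFTest (quasi-likelihood F test) gave p-values that were adjusted over the genes tested by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. Unless another tool is named, every adjusted p is from this test. Soldiers were compared with foragers over all bees with colony and strand batch as terms. The 9 differences within colonies were taken from a fit of the 18 group means with a shared estimate of the spread, and the interaction test asked whether these differences were equal. Differences between colonies were tested with behaviour and strand batch as terms. The colony scores belong to colonies, so their slopes were fitted on counts summed over the bees of each of the 9 colonies, and the interaction of the aggression score with behaviour on 18 sums. Standard errors (SE) of log2 fold changes were derived from the F statistics. Group levels are given as CPM, the count scaled to a TMM-adjusted library of 1000000, mean ± SD over bees.

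Gene lists fixed before the data were examined were tested with camera of limma 3.58.1, two-sided, with a preset correlation between genes and adjustment over the lists, where at least 5 members were tested; an estimated correlation was an alternative. Camera compares a list with the other genes. Fry, also run, tests whether the genes of a list move on balance one way and compares them with no other genes. The lists were immediate early genes, oxidative phosphorylation, glycolysis, biogenic amines, neuropeptides, insulin and nutrient signalling, juvenile hormone and ecdysteroid, odorant and chemosensory, head gland, retina, fat body and haemolymph, muscle, glia, Kenyon cell, immune, heat shock and chaperone, circadian clock, fast neurotransmission, cytochrome P450 and ribosomal protein. Members were found by symbol only, because the LOC genes carry no product names here. No member of the glycolysis list was found, and the oxidative phosphorylation list held the 13 genes encoded by the mitochondrion and no nuclear gene.

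The rule for naming genes was also fixed before the data were examined. For soldiers against foragers it took, per direction, the 8 called genes with the largest log2 fold change among those with a mean log2 CPM of at least 2 and the same sign in at least 7 of 9 colonies. It also took up to 2 called genes with the smallest adjusted p from each list, and Hr38, Egr1, Vg, Mrjp1 and Per whatever their test. Hr38 and Egr1 were not matched to a symbol, so 3 of these 5 are reported. For the score slopes it took the 5 genes per direction with the smallest p, for the interactions and each colony the 3 genes with the smallest p, and for the differences between colonies 5. Further list members are named only to say which genes a count holds; these were chosen after their values were seen.

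Each test was run on simulated data before the real counts, drawn from the real means and library sizes with known genes changed. For soldiers against foragers, simulated on 10010 genes, 95.5% of genes changed by 1.2-fold were recovered and 98.5% of those changed by 1.5-fold, and 5.8% of the calls fell on unchanged genes. Within 1 colony (10120 genes) the recovered shares were 44.8% at 1.2-fold and 82.1% at 1.5-fold. An effect present in 1 colony alone was recovered by the interaction test at 7.5% for 1.2-fold and 64.2% for 1.5-fold. A shift of 1 colony was recovered by the colony test (10018 genes) at 68.7% for 1.2-fold and 89.6% for 1.5-fold. A slope that spanned a 2-fold change over the range of the score was recovered at 92.5% for the aggression score (11069 genes), 92.5% for the consistency score (11068 genes) and 94.0% for the interaction with behaviour (10975 genes). The simulated colonies differed in no other gene. In every simulation the changed genes were drawn among genes above a minimum mean count. The recovered shares therefore do not hold for genes with few counts, which the real tests also include.

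Alternatives were DESeq2 1.42.0, size factors by the median ratio, other filters on low counts, no batch term, each batch alone, the replicate number as a block, each colony fitted alone, leaving out each colony, sums per colony and behaviour, scores by rank, and limma on colony means. Those chosen after seeing the data left out the shallow library, 9 bees with over 1% of counts on deformed wing virus, 3 bees with over 5% of counts on royal jelly protein genes, or 7 bees whose ND5 and ND1 levels were those of another colony; used the royal jelly protein percent as a covariate; or used edgeR's older quasi-likelihood method. To see what chance gives, behaviour labels were shuffled within colony and batch, colony labels within behaviour and batch, and scores among colonies, over 100 splits that include the real one, or 50 for the differences within colonies and their interaction. Exact and permutation tests were made in Python 3.11.15 with scipy 1.17.1. The bees are separate animals, but each colony was collected in a single session, so that a difference between colonies holds for these 9 collections and cannot be parted from the day of collection.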

Results

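The brains of 89 soldiers and 88 foragers were profiled by RNA sequencing. Soldiers were caught while stinging a leather target during a staged disturbance at the hive. Foragers left the hive in the same disturbance, were marked with talc, and were caught on their return with pollen after a rest. Behaviour is therefore confounded with the moment of collection, and with flight and delay, in every comparison of soldiers with foragers. The 9 colonies were Comerio, Patillas1, Patillas2, Penuelas2, Ponce2, Salinas1, Salinas2, St.Isabel1 and St.Isabel2, with 9 or 10 bees of each behaviour. Total counts ran from 6166138 to 19537168 per bee, apart from 24647 in Patillas2 soldier 9. The aggression score of the colonies ran from -5.31 in Salinas2 to 7.41 in Salinas1. The design allows 4 questions: which genes differ between soldiers and foragers, whether this depends on the colony, how colonies differ, and whether expression follows the colony's aggression or its consistency between assays.

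Genes for heat shock proteins were lower in the brains of soldiers than in those of foragers. All 4 members of the chaperone list fell, each in 9 of 9 colonies. Hsp90, the cytosolic chaperone that stabilises kinases and steroid receptors, had 2730 ± 776 CPM in soldiers (SD, n = 89) and 5280 ± 2550 CPM in foragers (SD, n = 88), a log2 fold change of -0.93 (SE 0.085, adjusted p = 4.47e-19). Hsc70-4, a constitutive chaperone of the Hsp70 family, changed by -0.48 (SE 0.053, adjusted p = 5.14e-14), Hsc70-3 by -0.48 (adjusted p = 2.03e-11) and the mitochondrial Hsc70-5 by -0.11 (adjusted p = 1.47e-06). In the antisense batch alone Hsp90 changed by -0.86 (adjusted p = 4.34e-08) and in the sense batch alone by -0.98 (adjusted p = 5.04e-10). The list was too short for camera. Adjusted over the list alone, the same 4 genes passed. Hsp90 lies on chromosome 7 from 9550759 to 9553976 and Hsc70-4 on chromosome 1 from 5356800 to 5361132.

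**Figure D1:**
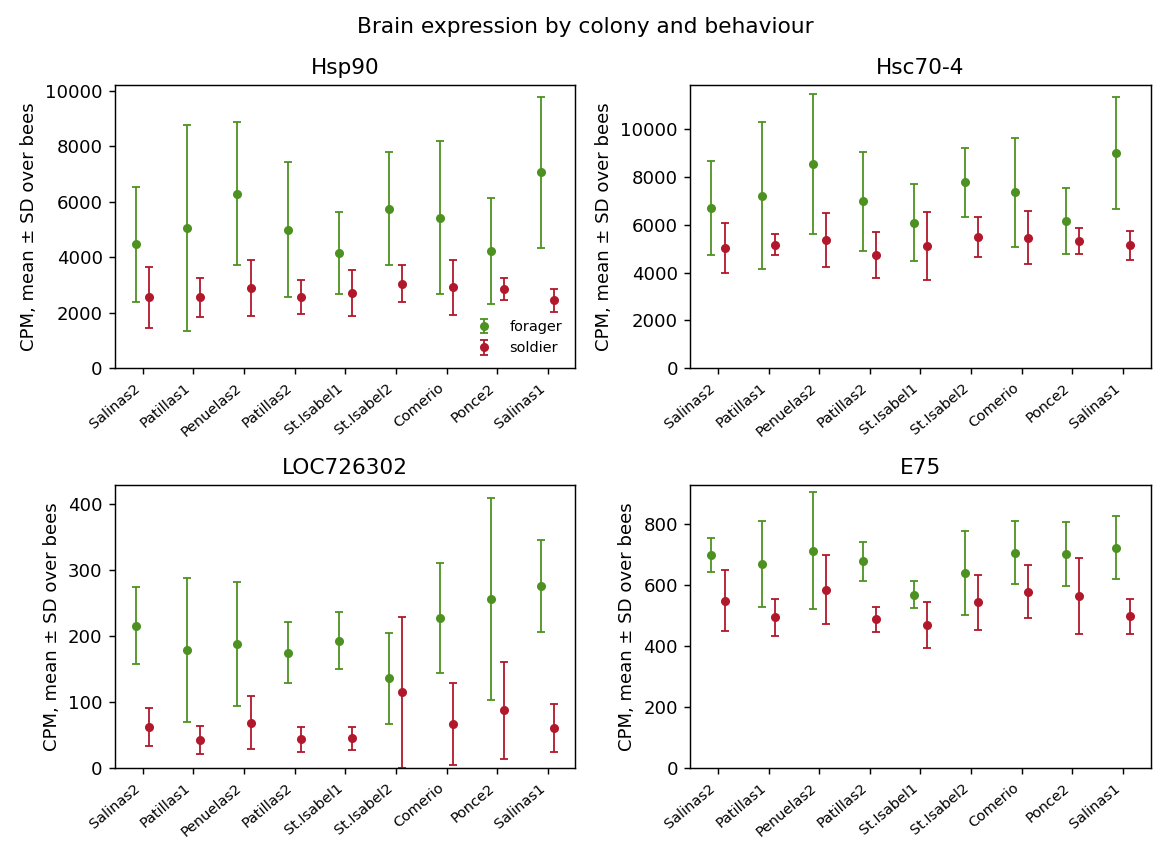
Expression of 4 genes (y axis, CPM) in each colony (x axis, from lowest to highest aggression score), with points for the mean and bars for the SD over the 9 or 10 bees of each behaviour, foragers in green and soldiers in red. The mean of Hsp90, Hsc70-4, LOC726302 and E75 was lower in soldiers in each of the 9 colonies; the difference of LOC726302 was smallest in St.Isabel2, at 115 CPM in soldiers and 136 CPM in foragers.

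Several receptor genes for amines and ecdysteroids were lower in soldiers. Of 11 biogenic amine genes, 6 fell and 0 rose, both over all genes and adjusted over the list alone. These were the dopamine receptors DopR2 (log2 fold change -0.34, SE 0.039, adjusted p = 1.04e-13), Dop1 (-0.12) and Dop3 (-0.11), the octopamine receptor Oa1 (-0.24, SE 0.040, adjusted p = 2.08e-07), and the serotonin receptors 5-HT1 (-0.06) and 5-HT2alpha (-0.11). DopR2 had 112 ± 21.4 CPM in soldiers (SD, n = 89) and 142 ± 28.9 CPM in foragers (SD, n = 88) and was lower in 9 of 9 colonies. The receptors TyrR (0.17, adjusted p = 0.0749), 5-ht7 (adjusted p = 0.376) and 5-HT2beta (adjusted p = 0.166) did not pass, nor did Tbh, which makes octopamine (adjusted p = 0.898), and Dat, the dopamine transporter (adjusted p = 0.651). In the sense batch alone Oa1 did not pass (-0.14, adjusted p = 0.0943). Camera gave the amine list an adjusted p of 0.0649, which did not pass; with an estimated correlation the adjusted p was 0.34, and fry gave 9.88e-11.

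Of 11 juvenile hormone and ecdysteroid genes, 3 fell and 1 rose. E75, an ecdysone-induced nuclear receptor, changed by -0.36 (SE 0.035, adjusted p = 4.33e-17), from 677 ± 117 CPM in foragers (SD, n = 88) to 530 ± 92.7 CPM in soldiers (SD, n = 89). The ecdysone receptor Ecr changed by -0.28 (SE 0.033, adjusted p = 9.58e-13), and both were lower in 9 of 9 colonies. The third was Vg, the yolk precursor vitellogenin, at -0.58 (SE 0.216, adjusted p = 0.0203), but it was higher in soldiers in 5 of 9 colonies and stood at 0.17 in the sense batch alone (adjusted p = 0.575). JHBP-1 rose by 0.95 (adjusted p = 0.0455), but was higher in soldiers in 5 of 9 colonies, with 9.59 ± 33.5 CPM in soldiers (SD, n = 89) and 5.12 ± 14.0 CPM in foragers (SD, n = 88). Adjusted over the list alone, 3 fell and 0 rose. Camera gave an adjusted p of 0.273, and 0.767 with an estimated correlation, whereas fry gave 0.000891.

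Among genes encoded by the mitochondrion and ribosomal protein genes, each called gene was higher in soldiers. Of 11 mitochondrial genes tested, 6 were higher in soldiers and 0 lower (8 and 0 adjusted over the list alone). Without 7 bees with the ND5 and ND1 levels of another colony, 5 were higher and 0 lower (5 and 0 adjusted over the list alone), and ND6 no longer passed. CYTB, a subunit of respiratory complex III, rose by 0.13 (SE 0.030, adjusted p = 0.000103), from 624 ± 119 CPM in foragers (SD, n = 88) to 689 ± 136 CPM in soldiers (SD, n = 89). ND5, a subunit of complex I, had a log2 fold change of 1.35 (SE 0.293, adjusted p = 5.01e-05), which fell to 0.25 (adjusted p = 0.00229) without these 7 bees. Of 7 ribosomal protein genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone), among them RpLP1 by 0.09 (adjusted p = 0.000153). Camera gave adjusted p = 0.101 for the mitochondrial and 0.0649 for the ribosomal list, each 0.767 with an estimated correlation, and fry gave 0.000477 for both. In all, camera passed 0 of 11 lists, of which 3 had an unadjusted p under 0.05, and fry, which asks whether the genes of a list move one way and compares them with no other genes, passed 4.

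In total 4645 of 9989 genes were called between soldiers and foragers, 2409 higher and 2236 lower in soldiers. Most differences were small: the median size of the called log2 fold changes was 0.102, and 26 called genes exceeded 1, of which 3 were higher and 23 lower. Of the called genes, 1428 had the same sign in all 9 colonies. The sense batch alone called 1967 genes, of which 1928 were among these, and the antisense batch alone 3856. Of the called genes named here for this comparison, CYTB, Crz, SIFR, RpLP1, LCCH3, Mrjp8, Or27, PGRP-S3, ND5 and LOC725309 did not pass in the sense batch alone, with adjusted p from 0.0522 for Mrjp8 to 0.522 for PGRP-S3.

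Among called genes with a mean log2 CPM of at least 2 and the same sign in at least 7 of 9 colonies, the 8 with the largest falls were LOC410620 (-1.85), LOC726302 (-1.72), LOC724367 (-1.65), LOC724488 (-1.60), LOC551232 (-1.40), LOC100576293 (-1.23), Lop2 (-1.10) and LOC725668 (-1.08). All except Lop2 were lower in 9 of 9 colonies. LOC726302, on chromosome 15 from 6242503 to 6270428, had the smallest adjusted p of these, 2.90e-27, with 66.2 ± 56.9 CPM in soldiers (SD, n = 89) and 205 ± 91.5 CPM in foragers (SD, n = 88). LOC724367 and LOC724488 lie close together on chromosome 2, starting at 4828926 and 4837466.

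Among called genes chosen by the same limits, the largest rises were in LOC412162 (2.68), ND5 (1.35), LOC725309 (0.74), LOC100577833 (0.59), LOC100576976 (0.52), LOC725942 (0.50), Cry2 (0.50) and LOC100576734 (0.46). Cry2, the cryptochrome that represses the insect clock, had 12.4 ± 6.06 CPM in soldiers (SD, n = 89) and 8.99 ± 4.63 CPM in foragers (SD, n = 88; adjusted p = 6.50e-07) and was higher in 7 of 9 colonies; in the sense batch alone its log2 fold change was 0.38 (adjusted p = 0.0545). Per, another clock gene, did not pass (0.05, adjusted p = 0.388), with 0.17 in the antisense batch alone (adjusted p = 0.0116) and -0.10 in the sense batch alone (adjusted p = 0.347), so that 1 of 2 clock genes rose, also adjusted over the list alone. LOC412162 varied widely, with 19.4 ± 37.4 CPM in soldiers (SD, n = 89) and 10.8 ± 30.1 CPM in foragers (SD, n = 88), and its sign turned in the sense batch alone (-0.41, adjusted p = 0.730). With counts summed per colony and behaviour, ND5 (adjusted p = 0.274), LOC725309 (adjusted p = 0.0983) and LOC412162 (adjusted p = 0.0565) did not pass.

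Receptors for fast transmitters split. Of 17 genes 3 rose and 6 fell, with the same counts adjusted over the list alone: the nicotinic subunit nAChRa8 rose by 0.12 (SE 0.014, adjusted p = 3.99e-13) in 9 of 9 colonies, and the GABA receptor subunit LCCH3 changed by -0.07 (SE 0.018, adjusted p = 0.000373). In the neuropeptide list 1 of 6 genes rose and 1 fell (the same adjusted over the list alone): the receptor SIFR by 0.10 (adjusted p = 0.00706) and the peptide corazonin, Crz, by -0.22 (adjusted p = 0.00255). Of 3 insulin genes the receptor InR-2 fell (-0.20, adjusted p = 5.30e-05), also adjusted over the list alone. Of 4 genes of Kenyon cells, the neurons of the mushroom bodies, the kinase genes Pkc (0.06, adjusted p = 0.00621) and Camkii (0.05, adjusted p = 0.0383) rose, both also adjusted over the list alone; in the sense batch alone neither passed (adjusted p = 0.250 and 0.411), and in the antisense batch alone Pkc passed (adjusted p = 0.0264) and Camkii did not (adjusted p = 0.0881).

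Markers of tissue that a dissected brain could carry showed few calls, except in the retina list, against 46.5% of all genes tested. Some had wide errors, such as Mrjp3 (log2 fold change 1.85, SE 1.045, adjusted p = 0.138). Few calls therefore do not show that soldiers and foragers carried such tissue equally. Of 14 head gland genes 1 passed, Mrjp8 at 0.18 (adjusted p = 0.000687), also adjusted over the list alone. Mrjp1, a royal jelly protein secreted by the hypopharyngeal gland, had a fitted log2 fold change of 1.07 that did not pass (SE 0.707, adjusted p = 0.212), while its mean was 2610 ± 6860 CPM in soldiers (SD, n = 89) and 5970 ± 41200 CPM in foragers (SD, n = 88); the forager mean rests on a few bees. In the antisense batch alone Mrjp1 stood at -0.09 (adjusted p = 0.955) and in the sense batch alone at 2.85, which passed (adjusted p = 0.0240). Of 4 retina genes the long-wavelength opsins Lop1 rose (0.34, adjusted p = 0.0496) and Lop2 fell (-1.10, adjusted p = 0.00140), both also adjusted over the list alone; in the antisense batch alone neither passed (adjusted p = 0.280 and 0.287), and in the sense batch alone Lop2 passed (adjusted p = 0.00661) and Lop1 did not (adjusted p = 0.162). Of 6 fat body genes Vg alone passed, also adjusted over the list alone. In the odorant list 1 of 31 rose and 4 fell (0 and 3 adjusted over the list alone), among them the odorant receptors Or170 (-0.71, adjusted p = 4.66e-06) and Or27 (-0.28, adjusted p = 0.00569), both under 1 CPM. Of 5 immune genes PGRP-S3 rose (0.13, adjusted p = 0.0304), and 0 adjusted over the list alone. By edgeR 0 of 2 muscle, 0 of 2 glial and 0 of 6 cytochrome P450 genes were called, also adjusted over the list alone, and the 1 immediate early gene found was too low to test. Camera gave adjusted p = 0.982 for the neuropeptide, odorant, head gland, fat body, immune, fast transmission and cytochrome P450 lists.

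Within single colonies the number of called genes ranged widely. Salinas1 had 2514 (1251 higher and 1263 lower in soldiers), St.Isabel1 1586, Salinas2 1546, Penuelas2 773, Patillas1 151, Patillas2 117, Ponce2 73, Comerio 57 and St.Isabel2 29, each of 10098 tested. The counts of each batch alone differed widely in some colonies. In the antisense batch alone Salinas1 had 1090 calls, St.Isabel1 560, Salinas2 1269, Penuelas2 401, Patillas1 5, Patillas2 11, Ponce2 0, Comerio 4 and St.Isabel2 16. In the sense batch alone Salinas1 had 497, St.Isabel1 68, Salinas2 1, Penuelas2 143, Patillas1 0, Patillas2 10, Ponce2 147, Comerio 0 and St.Isabel2 4. Without the shallow library (Patillas2 soldier 9) Patillas1 had 231 and Ponce2 115 calls, and without 9 bees rich in deformed wing virus Comerio had 25 and Salinas2 817. With each colony fitted alone, Comerio had 11 calls, Patillas1 1, Ponce2 20 and Penuelas2 0 by edgeR, the last with 1282 genes at an unadjusted p under 0.05. LOC726302 was among the 3 genes with the smallest p in Comerio (-1.77), Patillas1 (-2.07) and Patillas2 (-2.18), and LOC410620 in Comerio (-2.24) and Patillas1 (-2.40). LOC413825 was among them in Salinas1 (-0.65, adjusted p = 9.92e-10) and St.Isabel1 (-0.58, adjusted p = 1.85e-07). In Salinas1 the others were LOC100576805 (-0.51) and LOC409177 (-0.58), and in St.Isabel1 LOC412858 (-1.27) and LOC727423 (-1.51). In 1 or more colonies 4153 genes were called, and in 5 or more colonies 66.

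Some of the leading genes in the other colonies depended on a few bees. In Penuelas2 the first 3 were LOC413117 (-3.07), LOC724114 (-5.11) and LOC408361 (-2.11); without 3 bees of that colony that had over 5% of counts on royal jelly protein genes, its count dropped from 773 to 62 and LOC413117 stood at 0.06 (adjusted p = 0.941). In Salinas2 ND5 led (6.27), followed by LOC410874 (-0.50) and LOC412546 (0.38), and in Patillas2 ND1 (5.20) and ND5 (6.48); without the 7 bees with levels of another colony, ND5 stood at 0.50 in Salinas2 (adjusted p = 0.243) and 0.72 in Patillas2 (adjusted p = 0.326), and Salinas2 had 340 calls. In Ponce2 the first 3 were LOC551897 (-3.38), LOC409818 (-0.32) and LOC725958 (0.67), in St.Isabel2 LOC102655682 (5.35), LOC413083 (-7.58) and A4 (-3.25), and LOC100578814 led in Comerio (4.86) and LOC410410 rose in Patillas1 (0.79). LOC413083 had a mean of 270 CPM but a median of 0.175 CPM in St.Isabel2 foragers (n = 9).

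**Figure D2:**
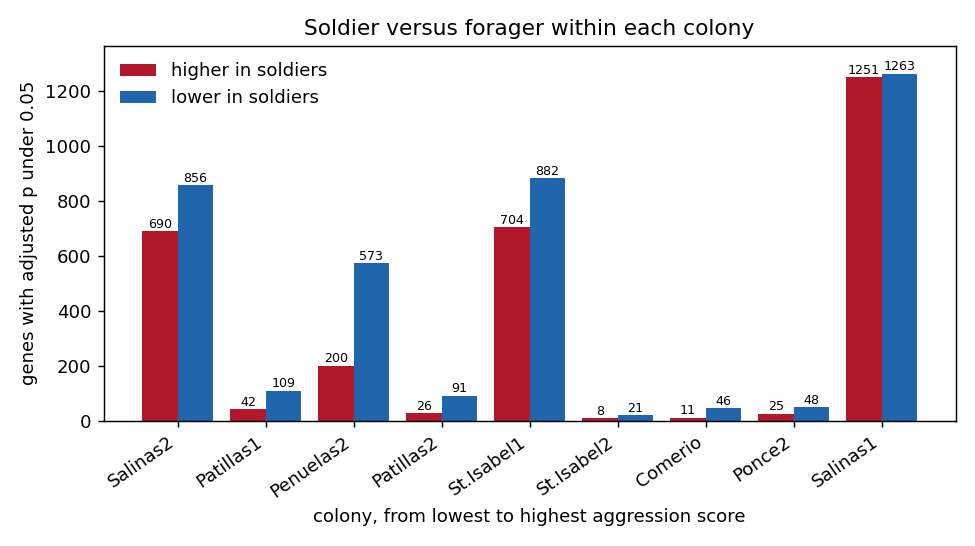
Number of genes with an adjusted p under 0.05 between soldiers and foragers (y axis) within each colony (x axis, from lowest to highest aggression score), with red bars for genes higher and blue bars for genes lower in soldiers. Salinas1 had the most calls, 1251 higher and 1263 lower, and St.Isabel2 the fewest, 8 higher and 21 lower.

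By the interaction test the size of the difference depended on the colony for 492 of 10098 genes. With behaviour labels shuffled, the same test called a median of 64 genes, so some of the 492 calls may be false. The mitochondrial genes ND5 (adjusted p = 3.93e-12) and ND1 (adjusted p = 1.52e-07) and the gene Apd-2 (adjusted p = 4.06e-09) led this test. Without the 7 bees with levels of another colony, chosen by these genes, ND5 (adjusted p = 0.849) and ND1 (adjusted p = 0.702) no longer passed, and Apd-2 did (adjusted p = 9.01e-08). The count was 784 without the shallow library, 293 without the 3 bees rich in royal jelly protein counts, 918 with DESeq2, 44 in the antisense batch alone and 15 in the sense batch alone; Apd-2 did not pass in the sense batch alone (adjusted p = 0.418).

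Of the 5 genes with the smallest p between colonies, 3 were mitochondrial. ND1, LOC100577912, LOC112935903, ATP6 and COX3 had the smallest p of 6356 genes called of 9989, with adjusted p from 3.66e-83 to 2.21e-58. ND5 had medians of 170 CPM in Salinas1, 187 CPM in Comerio and 220 CPM in Ponce2, and at most 1.34 CPM in the other 6 colonies. ND1, also of complex I, had medians between 16.3 and 32.9 CPM in 6 colonies and at most 0.071 CPM in Patillas1, Patillas2 and Penuelas2. ATP6 and COX3 were low in the same 3 colonies, with medians of at most 0.451 and 0.230 CPM against at least 17.6 and 14.5 CPM elsewhere. The most abundant mitochondrial gene, COX1, differed little, from 6374 CPM in Salinas2 to 8125 CPM in Comerio.

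LOC100577912, a nuclear gene on chromosome 15 from 8088264 to 8178048, fell into the same 3 sets of colonies; whether its counts come from sequence shared with the mitochondrion was not tested. Its mean in foragers was 319 ± 55.9 CPM in Patillas1 (SD, n = 10), 319 ± 49.9 in Patillas2 (SD, n = 10) and 312 ± 54.2 in Penuelas2 (SD, n = 10). It was 635 ± 42.4 CPM in Comerio (SD, n = 10), 612 ± 48.4 in Ponce2 (SD, n = 9) and 858 ± 560 in Salinas1 (SD, n = 10). In Salinas2, St.Isabel1 and St.Isabel2 it was 1610 ± 120 (SD, n = 10), 1750 ± 230 (SD, n = 10) and 1620 ± 200 CPM (SD, n = 9). LOC112935903 had medians of at least 2.12 CPM in both groups of Salinas1 and of at most 0.0568 CPM in every other group. The sense batch alone called 1897 genes between colonies.

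**Figure D3:**
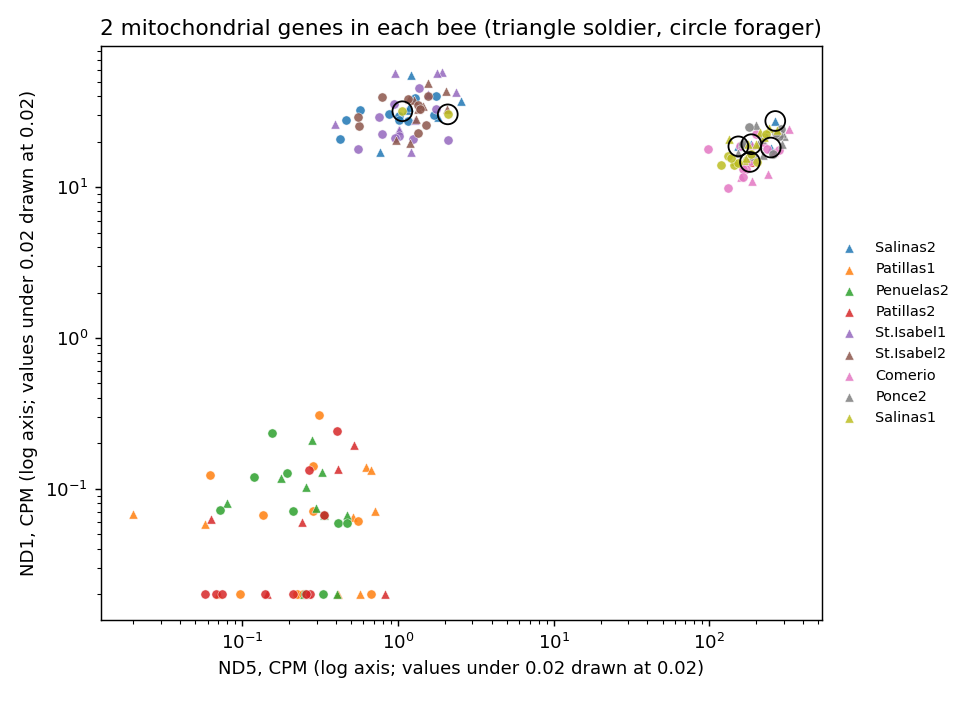
CPM of ND5 (x axis, log scale) and ND1 (y axis, log scale) in each of 176 bees, coloured by colony, with triangles for soldiers and circles for foragers. Bees fall into 3 separate clusters with no ND5 value between 2.53 and 97.4 CPM, and black rings mark 7 bees that lie in the cluster of another colony.

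With all bees and colonies, the quasi-likelihood test of edgeR called no gene for the colony scores, whereas its older method called 1 for consistency. Leaving out a colony gave 1 call for aggression without Salinas1 and 1 for consistency without Salinas2. For the aggression score 0 of 11065 genes were called, with 573 at an unadjusted p under 0.05 and 21 calls by DESeq2. For the consistency score 0 were called, with 584 at an unadjusted p under 0.05 and 43 calls by DESeq2. For the interaction of aggression with behaviour 0 of 10993 were called, with 300 at an unadjusted p under 0.05 and 0 by DESeq2. The lowest p for aggression belonged to LOC411052, which changed by -0.02 log2 units per unit of score (SE 0.003, adjusted p = 0.656), followed among lower genes by LOC551150, LOC412309, LOC412254 and LOC724612 and among higher genes by LOC409409 (0.06, adjusted p = 0.656), LOC112935903, Or12, LOC409463 and LOC725964. For consistency the lowest was LOC102654709 (-0.40, SE 0.043, adjusted p = 0.0515), next to LOC551553, LOC100578829, LOC412011 and LOC412885 on the lower side and LOC412057 (0.06, adjusted p = 0.467), LOC409467, LOC107964603, LOC100578353 and LOC413899 on the higher side. For the interaction LOC113218783, SP34 and LOC100578829 had the lowest p, all with adjusted p = 1.00.

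Of the lists, 2 passed camera in the direction of higher levels with the aggression score: the 13 mitochondrial genes (median slope 0.05 log2 units per unit of score; camera adjusted p = 1.70e-06) and the 7 ribosomal protein genes (median slope 0.01; camera adjusted p = 0.0130). The slopes of ND3 (-0.16) and CYTB (-0.0029) were below 0. With an estimated correlation neither passed (adjusted p = 0.788 for both, unadjusted p = 0.10 and 0.18), and fry passed 0 lists (0.820 for both). By edgeR 0 of the 13 and 0 of the 7 genes were called, also adjusted over the list alone. The other 9 lists tested did not pass camera, with adjusted p from 0.47 for cytochrome P450 to 0.995. Adjusted over the list alone, 1 gene of the hormone list passed on the lower side (Br-c, a transcription factor of the ecdysone response, unadjusted p = 0.00126) and 1 of the odorant list on the higher side (Or12, unadjusted p = 0.000569), and 0 in the remaining lists.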

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

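Chosen after the result was seen were the tests of a mitochondrial variant, of the library batches for ND5, of the family of the 7 bees and of exchanged colony labels, and every fit that left out the 7 bees or the bees rich in royal jelly protein counts.

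In each group of 9 or 10 bees, the total count, the percent of counts on mitochondrial genes and the percent on royal jelly protein genes were searched for a bee far from the others. Of 54 searches, 3 in each of 18 groups, 16 found such a bee, where chance alone gives about 1 in 20 for normally distributed values. That rate was not checked for the royal jelly protein percent, which is skewed. Patillas2 soldier 9 stood far below its group with 24647 counts, and Patillas1 forager 12 below its own with 10301640. The mitochondrial percent was high in Patillas1 forager 5 (1.09%), Patillas2 soldier 9 (1.69%) and St.Isabel2 forager 5 (0.929%). The royal jelly protein percent was high in 11 bees: Penuelas2 forager 4 (40.6%), Patillas2 soldier 7 (4.78%), Salinas1 soldier 8 (4.12%), St.Isabel1 soldier 1 (3.60%), Comerio forager 1 (3.35%), Ponce2 forager 10 (2.30%), Patillas1 soldier 10 (2.24%), Patillas1 forager 6 (1.14%), St.Isabel2 soldier 10 (0.979%), St.Isabel1 forager 4 (0.374%) and Patillas2 forager 6 (0.291%).

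The soldier and forager difference was unequal between colonies in 492 genes by the interaction test, with adjusted p = 3.93e-12 for ND5, 4.06e-09 for Apd-2 and 1.52e-07 for ND1. With behaviour labels shuffled within colony and batch, 1 of 50 splits, the real one, called as many genes. The others called a median of 64 genes and at most 165. The count was thus higher than under labels with no behaviour difference at all. Each of the 49 shuffled splits called genes, so an adjusted p under 0.05 admits false calls in this test. Shuffling also removes the difference that soldiers and foragers share over the colonies, so it cannot test equal differences alone.

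Virus features, which no gene test used, had counts in the antisense batch alone: deformed wing virus (DWV) in 84 of its 95 libraries, IAPV in 66 and VDV in 70, against 0 of 82 libraries of the sense batch for each. All 5 virus features were at 0 in the sense batch, and whether its libraries were counted against them in the same way is not known, so that these 0 counts do not show an absence of virus.

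The first pattern is the stepwise difference of mitochondrial genes between colonies. No bee lay between 2.53 and 97.4 CPM of ND5, a gap of 38.5-fold, while the colony medians of COX1 stayed within 1.28-fold of each other. A difference between the library batches is argued against, because ND5 passed the colony test in each batch alone (larger adjusted p = 2.52e-21). A candidate explanation is a mitochondrial sequence variant that keeps reads from aligning to the reference and is shared by the daughters of a queen; the gap and the level of COX1 are consistent with it, but no reads were used here to see a variant. A true difference in the level of these transcripts between colonies stays open as well and was not tested.

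The second pattern is 7 bees with the ND5 and ND1 levels of another colony: Patillas2 soldier 4, Salinas2 soldiers 1, 2, 4 and 8, and Salinas1 foragers 3 and 8. By 200 nuclear genes 0 of these 7 were nearest to their labelled colony, against 166 of the 169 other bees. This goes with bees of another family than their label. Patillas2 soldier 4 lay at a distance of 0.918 from Ponce2 and 1.53 from its label, and Salinas2 soldier 8 at 1.04 from Salinas1 and 1.54 from its label. The other 5 were less clearly placed, at 1.26 to 1.44 from the nearest colony. The 200 genes were those that differed most between colonies. LOC100577912, which follows the same sets of colonies as ND5 and ND1, was not kept out of that choice. The check may therefore not be independent of the levels that picked the bees. This matters most where distances are close, as in Salinas2 soldier 4 (1.31 from Comerio and 1.39 from its label). An exchange of labels between 2 soldiers is argued against, since 0 of the 30 soldiers of the colonies with their levels was out of place, and so is an exchange that carried the behaviour label along, since 7 of the 7 were nearest to their labelled behaviour. Workers that had drifted between hives at the common station and single wrong labels both stay open. Without these bees, which were chosen by the levels of the same genes, the interaction of ND5 had adjusted p = 0.849 (8.35e-20 to 0.849 over its alternatives) and that of ND1 0.702 (4.68e-11 to 0.702).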

How the results depend on the processing

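Chosen after seeing the data were the fits that left out the shallow library, the bees rich in virus or royal jelly protein counts or the 7 bees with levels of another colony, the royal jelly percent as a covariate, and the older quasi-likelihood method. The number of genes between soldiers and foragers stayed within 1.5 times 4645 under all alternatives except the sense batch alone (1967, in 82 libraries), where 1897 genes were called between colonies; leaving out a colony gave 3937 to 4776. Of 40 genes named for this comparison, 19 kept direction and side of the threshold under every alternative; over 1033 values 962 did so, 63 lost the call, 4 gained it and 4 reversed. These were LOC412162 (-0.405), Vg (0.167) and the uncalled Per (-0.10) in the sense batch alone, and the uncalled Mrjp1 (-0.091) in the antisense batch alone. In the interaction of aggression with behaviour the uncalled SP34 reversed with DESeq2 (-0.047). The interaction count was 279 with a mean CPM of at least 5, where fewer genes were tested, 44 in the antisense and 15 in the sense batch alone, 918 with DESeq2, 784 without the shallow library and 293 without the 3 bees rich in royal jelly protein counts. Each colony fitted alone gave 11 calls in Comerio, 1 in Patillas1, 0 in Penuelas2 (edgeR, with 1282 at an unadjusted p under 0.05) and 20 in Ponce2. It gave 2066 in St.Isabel1 and 1651 in Salinas2. Whether the smaller samples account for the falls was not tested. Without the shallow library Patillas1 had 231 and Ponce2 115 calls. Without the 9 virus-rich bees Comerio had 25 and Salinas2 817. Without the 3 gland-rich bees Penuelas2 had 62, and its gene LOC413117 reversed to 0.063. Without the 7 bees Salinas2 had 340. Salinas2 soldiers 2 and 4 were among both the virus-rich bees and the 7 bees, so the falls in Salinas2 cannot be parted. The aggression slope had 21 calls with DESeq2 and 0 to 1 on leaving out a colony (1 without Salinas1); the consistency slope had 43 with DESeq2, 0 to 1 on leaving out a colony (1 without Salinas2), 1 without the 7 bees and 1 with the older method. For aggression camera with an estimated correlation passed 0 lists in place of 2. Fry asks another question, without comparison to other genes, so its 4 lists for soldiers against foragers and 0 for aggression do not measure a dependence of camera. The sense batch held fewer libraries, and the filter on mean CPM left fewer genes to test. Whether these or other causes account for the changes was not tested. The low depth of Patillas2 soldier 9 left few counts for most genes, and leaving it out moved the counts given above.

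The replicate numbers did not pair the bees: over 76 pairs the deviations from the group means had a median correlation of -0.027 (range -0.434 to 0.430), 18 pairs were over 0.1, and 11 of 76 soldiers correlated best with their own number. With the replicate block the count between soldiers and foragers was 4152. Within colonies it was 5 in Comerio, 3 in Patillas1, 36 in Patillas2, 34 in Ponce2 and 4 in St.Isabel2. Of the leading genes of St.Isabel2, LOC413083 (adjusted p = 0.908) and A4 (adjusted p = 0.705) lost the call with this block, and LOC102655682 kept it (adjusted p = 1.14e-08). In Ponce2 LOC551897 lost the call (adjusted p = 0.441) and LOC409818 kept it.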

Other observations

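Chosen after the result was seen were the tests of ND5 against the aggression score and of calls against the aggression score, and the fit with the royal jelly protein percent as a covariate.

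Deformed wing virus reached a large share of the counts in some brains. In the antisense batch 9 libraries had over 1% of their counts on it, led by Comerio soldier 2 (21.7%), Salinas2 forager 2 (16.0%) and Salinas1 soldier 6 (15.1%), against a median of 11 counts. The mean log10(CPM + 1) was 0.171 higher in 48 soldiers than in 47 foragers, higher in 7 of 9 colonies, with a two-sided permutation p of 0.501 within colonies, which excludes neither a difference nor its absence, because 9 bees hold nearly all of the virus counts and the sense batch gave no value.

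The third pattern is the lower level of heat shock genes in soldiers. A difference between the library batches is argued against, since Hsp90 passed in each batch alone (-0.86 in the antisense and -0.98 in the sense batch, larger adjusted p = 4.34e-08). Head gland tissue rich in royal jelly protein transcripts is argued against as well. Hsp90 stood at -0.94 with the royal jelly protein percent as a covariate, against -0.93 without it. Gland tissue with few of these transcripts would escape this covariate and was not tested. Over its alternatives Hsp90 ran from -0.98 to -0.82, with adjusted p from 4.97e-23 to 0.000303. The behaviour itself, and the flight and delay before foragers were caught, stay open as untested. No forager was caught during the disturbance, so the design confounds behaviour with the moment of collection. The same limit applies to every gene called between soldiers and foragers.

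The 3 colonies with the highest aggression scores, Comerio, Ponce2 and Salinas1, were those with high ND5. Of the 84 sets of 3 colonies, 1 had a mean log2 ND5 as high (share 0.0119, exact, one-sided). A candidate explanation is a maternal line shared by the more aggressive colonies. However, relatedness may produce this with no role of the mitochondrion, 9 colonies are few, and the test was chosen on the same data. Over the 9 colony sums the slope of ND5 on the aggression score was 0.29 log2 units per unit of score, which did not pass (edgeR, unadjusted p = 0.148).

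No relation between the number of genes called within a colony and its scores was detected. Against the aggression score Pearson's r was -0.159 (exact permutation p = 0.674, n = 9 colonies) and Spearman's rho -0.150 (exact permutation p = 0.708); without Salinas1 and Ponce2 r was -0.674. Within the antisense batch r was -0.292 (exact permutation p = 0.436, n = 9) and within the sense batch 0.557 (exact permutation p = 0.125, n = 9). Against the consistency score r was -0.290 (exact permutation p = 0.439, n = 9) and rho -0.150 (exact permutation p = 0.708); without Patillas2 and Patillas1 r was -0.161, within the antisense batch -0.573 (exact permutation p = 0.106) and within the sense batch -0.344 (exact permutation p = 0.356). The adjusted p over these 2 relations was 0.674 for each. With 9 colonies a p above the threshold excludes neither relation.

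No likeness of colonies from the same coordinates was detected by colony profiles of 8730 genes. By the levels of ND5 and ND1, Patillas1 and Patillas2 fell into the same set of colonies. So did St.Isabel1 and St.Isabel2, whereas Salinas1 and Salinas2 did not. The mean correlation of colony profiles over the 3 pairs from the same place was -0.139, and 0.533 of the 1260 ways to choose 3 separate pairs gave a mean as high (exact, one-sided), which with 3 pairs excludes neither a likeness nor its absence.

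Chance can be excluded for the count of soldiers against foragers over all bees and for the count between colonies. With labels shuffled, 1 of 100 splits, the real one, reached 4645 genes between behaviours (highest other 20), and 1 of 100 reached 6356 genes between colonies (highest other 223). Within colonies the real labels alone, 1 of 50 splits, reached the count in Comerio (57, highest other 14), Patillas1 (151, 13), Patillas2 (117, 18), Ponce2 (73, 22), Salinas1 (2514, 287), Salinas2 (1546, 23), St.Isabel1 (1586, 34) and St.Isabel2 (29, 28). These shares were not adjusted over the colonies. Chance is not excluded in St.Isabel2, where a shuffled split nearly reached the count. In Penuelas2, 2 of 50 splits reached 773 genes, the real one and 1 that called 850, so chance is not excluded there either. The 850 calls point to a structure among its bees. Without its bees rich in royal jelly protein counts, the real labels called 62 genes, so most of the 773 calls depended on these bees. Whether these bees also account for the split that called 850 was not tested.

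Chance cannot be excluded for the scores. Of 100 assignments of the aggression score, 45 gave as many genes at an unadjusted p under 0.05 as the 573 seen (highest other 1106). For the consistency score 41 of 100 gave at least 584 (highest other 1315), and for the interaction of aggression with behaviour 87 of 100 gave at least 300 (highest other 1949). As many lists as the 2 that passed camera with the aggression score passed in 57 of 100 assignments (highest other 5).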
